A study of Mus musculus with 16 samples.

How the data were processed

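The samples were extracellular RNA from the culture supernatant of HCT116, a human colorectal carcinoma line. Per the labels, cells were exposed to X-rays at a high dose rate at 0, 2, 6 or 10 Gy and kept for 72 h in RPMI1640 medium with 10% fetal bovine serum. Each dose had 4 independent cultures, per the series' design text, giving 16 arrays in all. That text lists 0, 6 and 10 Gy, and the 2 Gy arrays were grouped by their own labels. The labels give the organism as mouse, whereas the line is human and the array carries probes for human miRNAs, so the values were read as human miRNAs. Small RNA was extracted with ISOGEN and 100 ng was labelled with Cy3, per the labels' protocols.

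Each deposited file holds the output of 1 single-colour Agilent miRNA array made with Feature Extraction 11.5.1.1, per the file headers. The processed signal is an intensity from which the scanner software had subtracted the background, with no scaling between arrays, per the file headers. The files also hold median spot and local background intensities, Agilent's total intensity per miRNA, and flags for outliers, saturation and detection, per the file headers. Each array had 56044 spots, 2164 of them controls, and 3523 probes for 1205 human and 142 viral miRNAs. Outlier-flagged spots made up 3.33 to 4.94% of the spots on an array, and no spot was saturated. Control and outlier-flagged spots were left out, and the remaining spots of a probe were averaged. The names are those of the array design, in which a suffix such as v16.0 marks a name from an older release, and the prefix hsa- is left out below.

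A probe counted as detected on an array where over 0.5 of its spots were well above background. Each array was divided by the 75th percentile of the signal over the 518 probes detected on all 16 arrays. A floor of 0.0412 in scaled units (log2 of -4.60) was then applied, the median over arrays of the 5th percentile of the detected probes' signal, and log2 was taken. Values at the floor have no order among themselves, so a fall that reaches it is understated. A miRNA was tested if at least 1 probe was detected on all 4 arrays of at least 1 dose, and its value was the mean over its probes that passed. This left 592 human probes and 283 human miRNAs, of whose values 4.20% lay at the floor. All levels below are log2 of scaled signal, and scaling removes any change shared by all miRNAs. The scaling and floor make levels comparable between arrays for 1 miRNA, not between miRNAs.

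Differences were fitted with limma 3.58.1 in R 4.3.3 (files were read with the data.table package, version 1.17.8), with lmFit and eBayes on all 16 arrays and a mean per dose, so that the doses shared 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over the 283 miRNAs, with a threshold of 0.05. Fitted in this way were 2, 6 and 10 Gy against 0 Gy, 10 Gy against 6 Gy, the slope per Gy, and a moderated F test of any difference among doses. Values with 1 number per array were compared with exact two-sided permutation tests of the 70 regroupings of 4 against 4 arrays, whose smallest p is 0.0286, and their p-values were adjusted over the 4 comparisons of a measure. Correlations across arrays carried permutation p-values, with 100000 resamples for 16 arrays and all 40320 orders for 8. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

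Before the data were examined, 15 lists of 158 miRNA names were fixed, of which 149 matched a name on the array and 9 did not. The 10 lists with at least 3 tested members were tested with limma's camera at its preset correlation, adjusted over the lists of a comparison, with an estimated correlation and with fry beside it. Results are given for 9 of these 10 lists, and the adjustment and the counts of lists are over all 10. The miR-200 family (2 tested members), the red blood cell list (1), and the white blood cell and platelet list (1) are given as values, and the miR-15/16 family and the serum-borne liver list had 0 tested members. The comparisons, alternatives and naming rule were fixed at the same time. The text names, per comparison, the 10 largest rises and 10 largest falls past the threshold whose 4 arrays of 1 dose lay on one side of the other dose's mean, or the smallest p-values up to 10 where fewer passed. For the 9 lists it also names every tested member of a list with 4 or fewer, otherwise the 4 with the largest change at 10 Gy, and the 5 brightest miRNAs. A miRNA detected on all arrays of 1 dose and none of another would have been named too, and 0 were found. A few others were chosen after their values were seen, as stated where they appear.

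The fit was tested on simulated data for 2 Gy against 0 Gy, with 60 of 283 miRNAs changed in 50 simulations. With independent noise it recovered 83.9% of log2 steps of 1 and 95.5% of steps of 2, with 4.04% false calls. With residuals of the real arrays resampled, the shares were 84.1%, 93.8% and 1.14%. The changed miRNAs were drawn at random, no floor was applied to the simulated values, and resampled residuals were spread over all doses. The shares do not carry over to the most variable miRNAs, such as miR-24-3p at 6 Gy (-2.66 ± 1.15, SE), which was not called. Nor do they cover false calls from arrays that stand apart from their dose. The precision of the real comparisons is limited by the 4 arrays per dose.

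The 16 arrays lay on 2 slides, each scanned by itself, with 0 and 2 Gy on slide 1 and 6 and 10 Gy on slide 2. On each slide the lower dose filled the left side and the higher dose the right. Dose and slide cannot be told apart for 6 or 10 Gy against 0 Gy. The comparisons of 2 Gy with 0 Gy and 10 Gy with 6 Gy lie within a slide but between its sides. Replicate numbers in the labels were checked for pairing and did not pair the arrays over all doses. Checked by dose after seeing the data, all 4 same-number pairs of 6 and 10 Gy had correlated deviations (0.23 to 0.72). The labels name no shared batch, and the number also follows the slide row. The alternatives concerned background correction, scaling, the floor, the probe filter, the summary over probes, the variance model, array weights, blocks for replicate number, slide row and slide, the arrays fitted, and leaving out each array. A labelling spike-in covariate, a fit of the 6 and 10 Gy arrays in pairs and fits without the arrays in doubt were added after seeing the data. Normexp on mean spot signals was not run, because that column is not used here, and normexp on the median signals took its place. No reference genome was used and no coordinates are given.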

Results

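Extracellular miRNAs of HCT116 colorectal carcinoma cells were measured 72 h after X-rays at 0, 2, 6 and 10 Gy, with 4 cultures per dose and 1 array per culture. Arrays detected between 242 and 358 of the 1205 human miRNAs, with means of 327.5 ± 22.5 at 0 Gy, 300.5 ± 36.2 at 2 Gy, 296.5 ± 28.4 at 6 Gy and 293 ± 35.1 at 10 Gy (SD, n = 4). None of these differences passed an exact two-sided permutation test, the smallest p being 0.143 (adjusted 0.286) for 6 and for 10 Gy against 0 Gy. With 1 array left out, p fell to 0.0286, the smallest that 3 against 4 arrays can give, at 2 Gy (without its replicate 2), 6 Gy (without its replicate 2) and 10 Gy (without its replicate 1). The unscaled 75th percentile of the detected probes was 8.84 ± 0.35, 8.95 ± 0.35, 9.09 ± 0.44 and 8.61 ± 0.31 on the log2 scale at 0, 2, 6 and 10 Gy (n = 4 each). The smallest p for this level was 0.114 (adjusted 0.457, exact two-sided permutation test), for 10 Gy against 6 Gy. Leaving out 1 array brought the p of this comparison down to 0.0286 at the lowest, the smallest that 3 against 4 arrays can give. The 5 brightest miRNAs over all arrays were miR-4281 (7.08), miR-762 (5.92), miR-1225-5p (4.87), miR-1207-5p (4.80) and miR-1202 (4.34), all 5 in the list of GC-rich or purine-rich miRNAs. This is an order of probe signal, not of amount, as levels are not comparable between miRNAs, and no enrichment was tested.

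Agilent's labelling spike-in RNA, added at the labelling step, lay in the software's range on 3 of the 16 arrays, and the hybridisation spike-in on all 16. The labelling spike-in averaged 6.69 ± 4.00 on the log2 scale at 0 Gy, 5.02 ± 1.84 at 2 Gy, 3.82 ± 2.63 at 6 Gy and 6.93 ± 1.13 at 10 Gy (SD, n = 4). At least 1 labelling spike-in was undetected on 4 arrays. It moved with the mean of 21 tested miRNAs from the let-7, miR-17-92, miR-200, colorectal cancer, miR-23/27/24 and miR-29/30 lists. This mean was not among the comparisons fixed beforehand. Over the 16 arrays Pearson's r was 0.84 (permutation p = 2e-05, adjusted 4e-05) and Spearman's rho 0.90 (p = 2e-05, adjusted 8e-05), where 2e-05 is about the smallest that 100000 resamples gave. Within slides r was 0.80 on slide 1 (exact permutation p = 0.021) and 0.94 on slide 2 (exact permutation p = 0.00017), and rho was 0.71 (p = 0.058) and 0.98 (p = 0.0004). For deviations from the dose means r was 0.86 (permutation p = 2e-05). Without the 2 arrays farthest from the median spike-in, r over all arrays was 0.88.

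**Figure D1:**
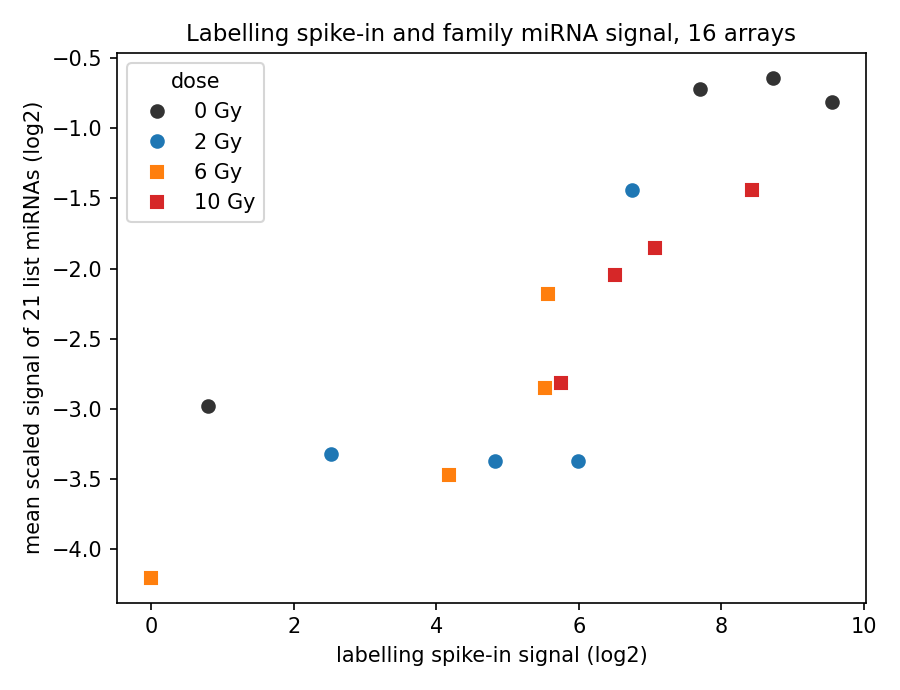
Log2 signal of the labelling spike-in (x axis, signals under 1 set to 1) against the mean log2 scaled signal of 21 list miRNAs (y axis), 1 point per array, with colour for dose, circles for slide 1 and squares for slide 2. The 0 Gy arrays lie highest except replicate 3, whose spike-in was 0.80 and whose mean was -2.98.

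The study's title asks which extracellular miRNAs depend on dose. At 2 Gy, the lowest dose above 0, the largest changes were falls. miR-125b-5p fell by 3.53 ± 1.06 (SE) on the log2 scale, from -0.17 ± 2.18 to -3.70 ± 1.79 (SD, n = 4 each; adjusted p = 0.0417). miR-25-3p, of the miR-106b-25 cluster, fell by 3.25 ± 0.93 (adjusted p = 0.0350), miR-100-5p by 2.82 ± 0.79 (0.0333) and miR-21-5p, an oncogenic miRNA raised in many carcinomas, by 2.79 ± 0.66 (0.0225). On 3 of the 4 arrays at 2 Gy miR-125b-5p, miR-100-5p, miR-21-5p, miR-221-3p and miR-1274a_v16.0 lay at the floor, and miR-25-3p at or just above it. The falls of these miRNAs are therefore understated. miR-125b-5p, miR-100-5p and miR-21-5p were each detected on 1 of 4 arrays at 2 Gy and on all 4 at 0 Gy. miR-1246 fell by 2.18, miR-221-3p by 2.03, miR-1290 by 1.60, miR-494-3p by 1.55, miR-1274a_v16.0 by 1.53 and miR-4286 by 1.52. Rises were smaller. miR-516a-5p rose by 0.94 ± 0.21 (SE; adjusted p = 0.0190), miR-765 by 0.82 ± 0.18 (0.0190) and miR-30c-2-3p by 0.74 ± 0.20 (0.0283). miR-3605-5p rose by 0.64, miR-149-3p by 0.63, miR-483-5p by 0.62, miR-711 by 0.61, miR-371a-5p by 0.58, miR-373-5p by 0.50 and miR-134-5p by 0.49.

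By list, 2 of the 10 tested lists were lower at 2 Gy with camera's preset correlation and 0 with an estimated one (adjusted p = 0.447 for each of the 2). With the preset correlation the number was 6 without scaling, 6 with quantile normalization and 7 with scaling over all probes. The miR-23, miR-27, miR-24, miR-221 and miR-222 clusters had a median of -1.89 over 6 tested members (adjusted p = 0.00387), with miR-221-3p called, and 5 members passed when adjusted over the list alone. miR-24-3p (-2.46), miR-27a-3p (-1.88), miR-23a-3p (-1.60) and miR-27b-3p (-1.17) did not pass over all miRNAs. The list of names later assigned to fragments of other non-coding RNAs had a median of -1.11 over 6 members (adjusted p = 0.00387). In it miR-1246, miR-1260b (-1.49) and miR-1274a_v16.0 were called, 5 members passed when adjusted over the list alone, and miR-1274b_v16.0 (-0.72) did not pass over all miRNAs. With fry the fragment list kept an adjusted p = 0.0256 and the cluster list had 0.0585. No member of the let-7 family (let-7b-5p -1.32, let-7c-5p -1.55, let-7i-5p -1.01) or the miR-200 family (miR-200c-3p -2.14, miR-141-3p -0.82), regulators of differentiation and of epithelial identity, passed. In the miR-17-92 list miR-25-3p fell, and miR-93-5p (-1.46), miR-92a-3p (-1.20) and miR-17-5p (-1.07) did not pass. In the colorectal cancer list miR-21-5p fell, and miR-31-5p (-1.37) and miR-183-5p (-1.03) did not pass. In the DNA repair list miR-100-5p fell and miR-210-3p (-1.53), the hypoxia-induced miRNA, did not pass. miR-30e-5p fell by 1.13 (adjusted p = 0.0225), while miR-29a-3p (-2.48) and miR-30d-5p (0.24) did not pass. In the GC-rich list of 30, 3 members were higher and 1 lower, against 15 and 1 with scaling over all probes and 3 and 2 with quantile normalization, among them miR-134-5p and miR-188-5p (0.45, adjusted p = 0.0333) against miR-494-3p, and miR-1234-3p (-0.25) did not pass. Markers of other cell types did not pass, with 0.15 for miR-486-5p (red blood cell), 0.19 for miR-155-5p (white blood cell), and -0.35, 0.12 and 0.09 for the muscle miRNAs miR-206, miR-133a-3p and miR-133b, whose list median (0.09) and mean (-0.05) differ in sign. The labelling spike-in, which moved with the mean of 21 list miRNAs across arrays, differed by -1.67 on the log2 scale from 0 Gy (exact two-sided permutation p = 0.486, adjusted 0.648).

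In all, 36 of 283 miRNAs differed at 2 Gy (limma, 99 at an unadjusted p under 0.05), 17 higher and 19 lower, against 111 higher and 18 lower of 129 with scaling over all probes, 55 and 16 of 71 with quantile normalization, and 0 without scaling (36 at an unadjusted p under 0.05). The count was 0 without 2 Gy replicate 1 or 2 Gy replicate 4 or with the 8 arrays of slide 1 alone (69 at an unadjusted p under 0.05 in each), 3 without 0 Gy replicate 1, 6 without 2 Gy replicate 3, 14 and 21 without 0 Gy replicates 4 and 2, 55 without 6 Gy replicate 4, 87 without 2 Gy replicate 2, 121 without 0 Gy replicate 3, and, as chosen after seeing the data, 152 without both of these arrays.

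**Figure D2:**
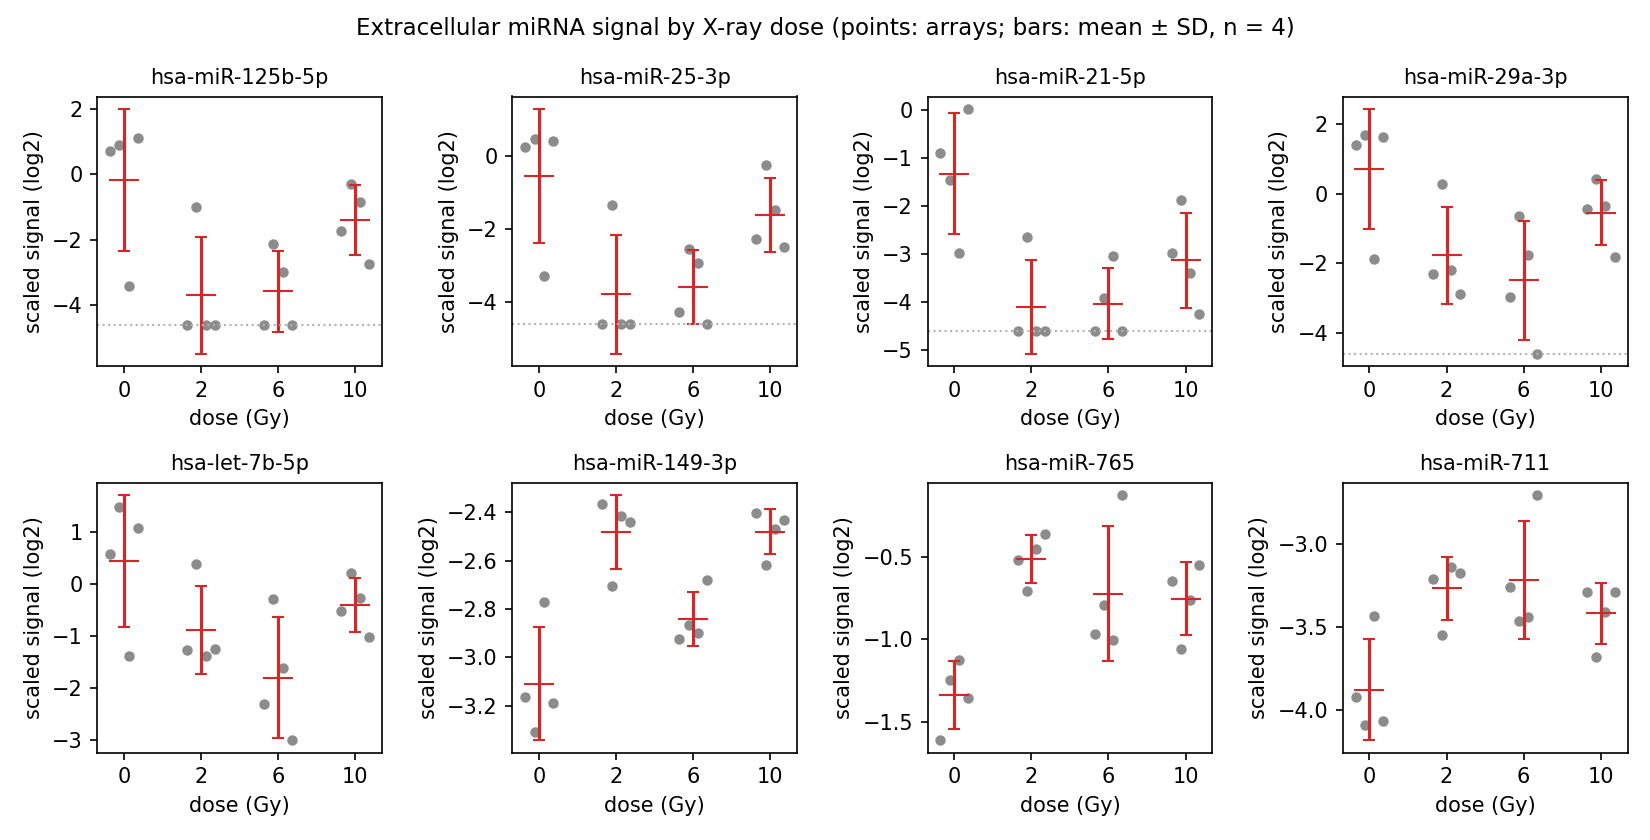
Log2 scaled signal (y axis) by dose in Gy (x axis) for 8 miRNAs, with grey points for arrays, red bars for the mean ± SD (n = 4 per dose) and a dotted line at the floor of -4.60. The 0 Gy mean of miR-125b-5p was -0.17 with replicate 3 at -3.43, and at 2 Gy replicate 2 alone lay above the floor, at -1.01.

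At 6 Gy the falls included the let-7 family. let-7b-5p fell by 2.24 ± 0.65 (SE; adjusted p = 0.0407), let-7c-5p by 2.24 ± 0.68 (0.0407) and let-7i-5p by 1.92 ± 0.53 (0.0353), and all 3 tested members of this differentiation-linked family passed. miR-125b-5p fell by 3.41 ± 1.06 (SE), miR-29a-3p, which targets collagen transcripts, by 3.20 ± 0.96, miR-25-3p by 3.04 ± 0.93 and miR-21-5p by 2.72 ± 0.66, with adjusted p-values of 0.0407, 0.0407, 0.0407 and 0.0304. miR-29a-3p went from 0.71 ± 1.73 to -2.49 ± 1.70 (SD, n = 4 each). miR-100-5p fell by 2.43, miR-210-3p by 2.29, miR-27a-3p by 2.12 and miR-425-5p by 2.06. Among the rises, miR-30c-1-3p rose by 0.84 ± 0.26 (adjusted p = 0.0407), miR-711 by 0.66, miR-3195 by 0.62, miR-765 by 0.61 and miR-134-5p by 0.55. miR-150-3p rose by 0.52, miR-601 by 0.48, miR-557 by 0.47, miR-1207-5p by 0.45 and miR-1226-5p by 0.40.

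By list, 7 of 10 were lower at 6 Gy with the preset correlation. These were the let-7 family (median -2.24, adjusted p = 0.0327), the DNA repair list (-2.43, 0.0399), the miR-17-92 list (-1.62, 0.0367), the colorectal cancer list (-1.69, 0.0399), the miR-23, miR-27, miR-24, miR-221 and miR-222 clusters (-1.70, 0.0120), the miR-29 and miR-30 families (-1.32, 0.0460) and the fragment list (-0.93, 0.0120). Each had an adjusted p = 0.301 with an estimated correlation, and fry called the same 7. The estimated correlations ran from 0.58 (fragments) to 0.96 (let-7) over the 7 lists, and the preset p-values do not allow for them. miR-24-3p is in both the DNA repair and the cluster list, so the 7 are not separate results. Called members numbered 3 of 3 for let-7, 2 of 3 for DNA repair, 1 of 4 for miR-17-92, 1 of 3 for colorectal cancer, 3 of 6 for the clusters, 2 of 3 for miR-29/30 and 3 of 6 for the fragments. Adjusted over the list alone, the numbers were 3, 3, 4, 2, 6, 2 and 4. Among the cluster members miR-27b-3p fell by 1.26, while miR-24-3p (-2.66) and miR-23a-3p (-1.52) did not pass. miR-30e-5p fell by 1.32 and lay at the floor on all 4 arrays, while miR-30d-5p (-0.23) did not pass. In the fragment list miR-1246 fell by 1.97, miR-1274a_v16.0 by 1.67 and miR-1260b by 1.15, and miR-1274b_v16.0 (-0.71) did not pass. Values that did not pass were those of miR-17-5p (-1.65), miR-93-5p (-1.59), miR-92a-3p (-1.13), miR-31-5p (-1.69), miR-183-5p (-1.19), miR-200c-3p (-2.50, adjusted p = 0.0514) and miR-141-3p (-2.07, 0.0570). The GC-rich list had 3 members higher and 4 lower, against 19 and 3 with scaling over all probes and 5 and 5 with quantile normalization, with miR-494-3p falling by 1.64, and miR-188-5p (0.35) and miR-1234-3p (-0.02) not passing. Among other cell types miR-155-5p, abundant in lymphocytes, rose by 0.31 ± 0.09 (SE; adjusted p = 0.0407). No other member of the white blood cell and platelet list was detected on any array, so this rise does not show such cells. Values for miR-486-5p (0.21), miR-206 (-0.53), miR-133a-3p (0.31) and miR-133b (0.31) did not pass. The other red blood cell members and miR-1-3p of the muscle list were not detected on any array. The labelling spike-in differed by -2.87 from 0 Gy (exact two-sided permutation p = 0.314, adjusted 0.629).

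In all, 55 miRNAs differed at 6 Gy (118 at an unadjusted p under 0.05), 17 higher and 38 lower, against 148 and 29 of 177 with scaling over all probes, 92 and 35 of 127 with quantile normalization, 0 without scaling (62 at an unadjusted p under 0.05) and 2 with the labelling spike-in as a covariate. Dose and slide cannot be told apart here, and the count was 0 without 0 Gy replicate 1, 2 or 4 or 6 Gy replicate 1 or 4 (90 to 104 at an unadjusted p under 0.05), 11 without 2 Gy replicate 1 or 10 Gy replicate 3, 17 without 10 Gy replicate 1, 19 without 6 Gy replicate 3, 24 without 2 Gy replicate 3 or 4, 143 without 0 Gy replicate 3, and, as chosen after seeing the data, 166 without that array and 2 Gy replicate 2.

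At 2 and at 6 Gy 18 miRNAs were called lower and 5 higher at both doses, an overlap that the shared 0 Gy arrays raise and that was not tested. Across miRNAs the fold changes of 2 and 6 Gy correlated at r = 0.95, with a covariance of 0.51. Both used the same 0 Gy arrays, and unchanged groups simulated against shared controls gave a mean r of 0.43 with a 97.5th percentile of 0.967, so r lay within the range without change. Their mean covariance was 0.05, and 1 of 1000 simulations gave a covariance as large as the measured one. With the 0 Gy arrays split between the comparisons, r averaged 0.85 and ranged from 0.73 to 0.93. miRNAs are not independent replicates of one another.

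At 10 Gy, the highest dose, miR-149-3p was the 1 miRNA that passed. This arm of the miR-149 precursor rose by 0.63 ± 0.12 (SE), from -3.11 ± 0.23 to -2.48 ± 0.09 (SD, n = 4 each; adjusted p = 0.0272), with all 4 arrays at 10 Gy above all 4 at 0 Gy, as it did at 2 Gy (0.63, adjusted p = 0.0190) but not at 6 Gy (0.27, 0.0964). The next 9 by p did not pass, with 0.56 for miR-3605-5p, 0.52 for miR-134-5p, 0.45 for miR-1226-5p, 0.45 for miR-601, 0.39 for miR-3610, -1.18 for miR-1260b, -1.04 for miR-30e-5p, -0.56 for miR-365a-3p and -0.44 for miR-92b-3p, and adjusted p-values from 0.0530 to 0.0616. The miRNAs with the largest falls at lower doses did not pass at 10 Gy, with -1.80 ± 0.66 (SE) for miR-21-5p, -1.25 ± 0.96 for miR-29a-3p, -1.08 ± 0.93 for miR-25-3p and -1.04 ± 0.79 for miR-100-5p. let-7b-5p was at -0.84, let-7i-5p at -0.75 and let-7c-5p at -0.74.

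The fragment list was the 1 of 10 lists that passed at 10 Gy, against 3 with scaling over all probes (the colorectal cancer list at an adjusted p of 0.0395, the clusters at 0.0131 and the fragments at 0.000601), with a median of -0.70 (adjusted p = 0.00393 with the preset correlation), and miR-1274a_v16.0 at -0.998, miR-1246 at -0.84 and miR-1274b_v16.0 at -0.55. Its adjusted p = 0.602 with an estimated correlation and 0.132 with fry, and 2 members passed when adjusted over the list alone. In the cluster list miR-27a-3p (-1.40), miR-24-3p (-1.14), miR-27b-3p (-0.88) and miR-23a-3p (-0.61) did not pass, nor did miR-210-3p (-0.85), miR-31-5p (-0.90), miR-183-5p (-0.36), miR-17-5p (-0.63), miR-93-5p (-0.58), miR-92a-3p (-0.18), miR-200c-3p (-0.74), miR-141-3p (-0.53) or miR-30d-5p (0.35). Of the GC-rich list, whose median of 0.07 was -0.17 without scaling and 0.28 with scaling over all probes, none passed, with -0.82 for miR-494-3p, 0.44 for miR-188-5p and -0.46 for miR-1234-3p. With scaling over all probes 2 members were higher and 0 lower, and with quantile normalization 0 were called. Markers of other cell types did not pass, with 0.31 for miR-486-5p, 0.27 for miR-155-5p, -0.33 for miR-206, -0.17 for miR-133a-3p and -0.15 for miR-133b, whose list median (-0.17) was 0.02 with quantile normalization and with scaling over all probes. The comparison gave 63 miRNAs at an unadjusted p under 0.05, and its single rise compares with 20 higher and 2 lower of 22 with scaling over all probes, 25 and 2 of 27 with quantile normalization, and 56 calls (34 higher, 22 lower) with the labelling spike-in as a covariate. No miRNA was called without scaling (22 at an unadjusted p under 0.05), with normexp (37) or with Agilent's total signal (59). Dose and slide cannot be told apart, and the count was 0 without 0 Gy replicate 1 or 4, 2 Gy replicate 4, 6 Gy replicate 2 or 10 Gy replicate 1, 3 or 4 (39 to 59 at an unadjusted p under 0.05), 2 and 9 without 6 Gy replicates 1 and 4, 11 without 0 Gy replicate 2, 43 without 0 Gy replicate 3, and, as chosen after seeing the data, 70 without that array and 2 Gy replicate 2.

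**Figure D3:**
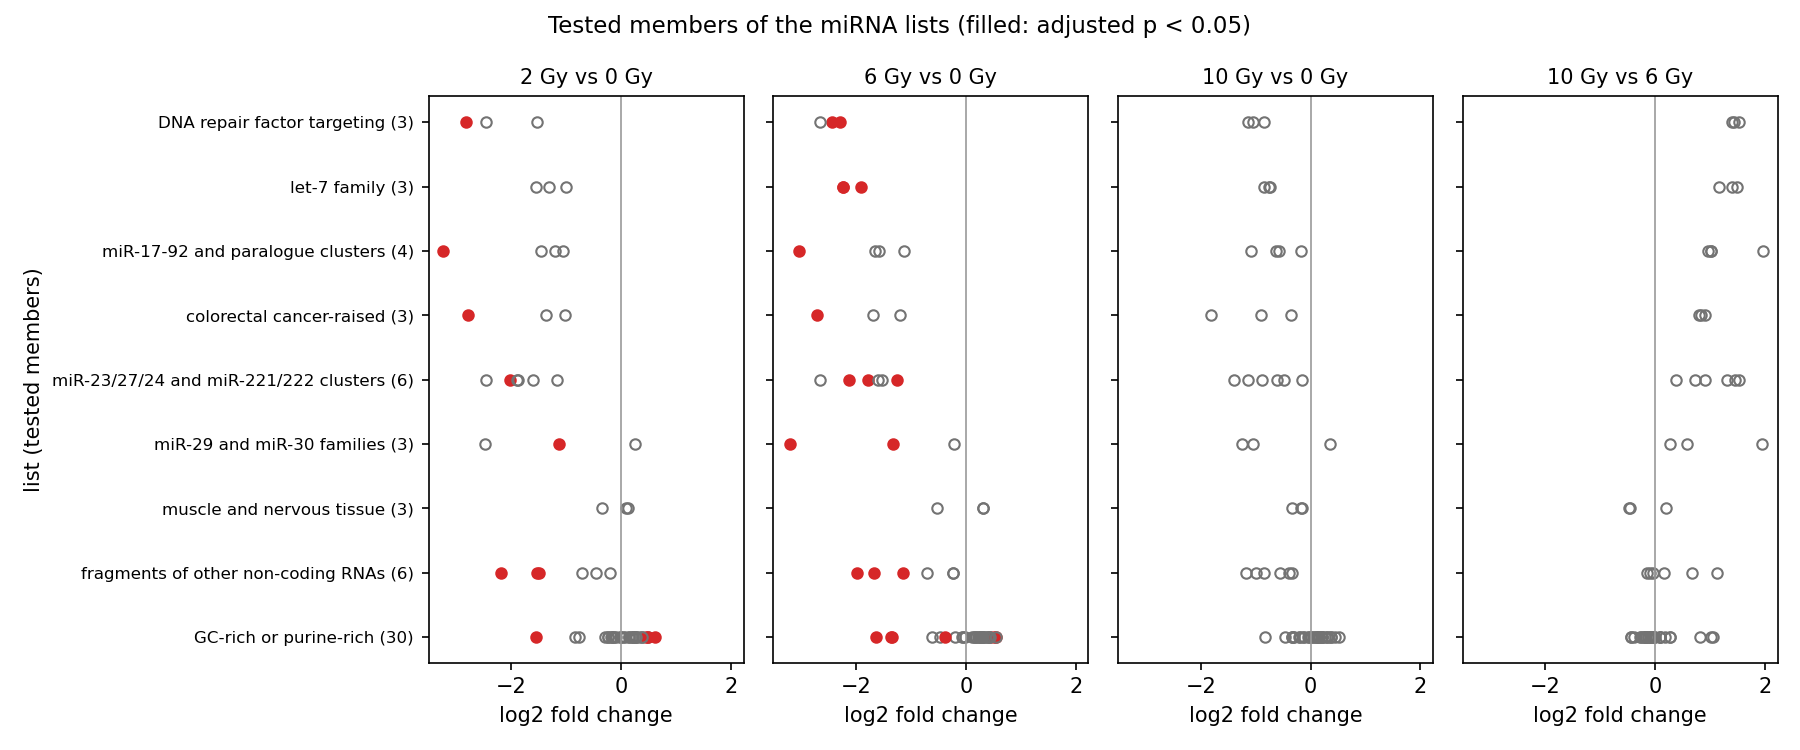
Log2 fold change (x axis) of each tested member of 9 lists (y axis, number of tested members in parentheses) in the 4 comparisons between doses, with filled red points for an adjusted p under 0.05 and open points otherwise. At 6 Gy the 3 let-7 members lie between -2.24 and -1.92, and at 10 Gy the points shown are open, while miR-149-3p (0.63), which is in none of these 9 lists, passed.

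Between 10 and 6 Gy, which share a slide, no miRNA passed in the unblocked fit. In a fit of these 8 arrays in pairs of equal replicate number, chosen after seeing the data, 55 passed (36 higher, 19 lower; 121 at an unadjusted p under 0.05). The labels do not say that the numbers mark a shared batch. The paired count was 3 to 38 with 1 pair left out, and 0 for the same 8 arrays with the slide row as the block (66 at an unadjusted p under 0.05) or with no block. In the unblocked fit the values at 10 Gy lay above those at 6 Gy for miR-25-3p (1.96 ± 0.93, SE), miR-29a-3p (1.94 ± 0.96), miR-200c-3p (1.76 ± 0.85), miR-141-3p (1.54), miR-24-3p (1.52), let-7c-5p (1.49), miR-210-3p (1.44), let-7b-5p (1.40), miR-100-5p (1.39) and let-7i-5p (1.17), with adjusted p-values from 0.321 to 0.398. All of these but miR-24-3p passed in pairs, where the smallest p-values belonged to miR-221-3p (1.30), miR-25-3p (1.96) and miR-125b-5p (2.18), with adjusted p-values of 0.00474, 0.00474 and 0.00649. The 10 smallest p-values, each with an adjusted p of 0.321, belonged to miR-551b-5p (1.00), miR-3621 (0.24), miR-149-3p (0.36), miR-320e (1.01), miR-339-3p (0.53), miR-320d (1.05), miR-3180-5p (-0.41), miR-181b-5p (0.60), miR-708-5p (0.67) and miR-3617-5p (0.50), all but miR-3621 passing in pairs. The muscle miRNAs miR-133a-3p (-0.48) and miR-133b (-0.46) lay lower at 10 Gy and did not pass over all miRNAs in the unblocked fit, though both passed when adjusted over the list alone, as did the 3 let-7 members. In pairs these 5 passed over all miRNAs, the muscle miRNAs at 0.0394 and 0.0399 (adjusted p). Unblocked, no list passed, the smallest adjusted p of the 9 lists being 0.0512 with the preset correlation and 0.390 with an estimated correlation, whereas 7 lists passed without scaling, 7 with scaling over all probes and 4 with quantile normalization. In pairs 5 of 10 passed with the preset correlation, 0 with an estimated one (smallest adjusted p = 0.294) and 7 with fry. The labelling spike-in was higher at 10 Gy by 3.12 on the log2 scale (exact two-sided permutation p = 0.0286, the smallest possible, adjusted 0.114). Unblocked, limma gave 0 calls with 42 at an unadjusted p under 0.05.

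No miRNA followed the dose in a straight line past the threshold. The smallest p-values for the slope belonged to miR-3610 (0.03 ± 0.01 log2 per Gy, SE), miR-769-3p (0.03), miR-422a (0.04), miR-939-5p (0.03), miR-99b-3p (0.02), miR-423-5p (0.03), miR-486-5p (0.03), miR-500a-5p (0.04), miR-663b (-0.08) and miR-663a (-0.03), each with an adjusted p = 0.280. miR-3610 averaged 0.15, 0.41, 0.51 and 0.55 at 0, 2, 6 and 10 Gy. The fragment list had a median slope of -0.04 per Gy (adjusted p = 0.0366 with the preset correlation, adjusted p = 0.692 with an estimated correlation), and -0.05 with the slide as a block (adjusted p = 0.271). The slope gave 0 calls in limma (36 at an unadjusted p under 0.05), and 0 with the slide as a block (24). The F test of any difference among doses gave 0 calls (91 at an unadjusted p under 0.05, smallest adjusted p = 0.0529), but 104 with scaling over all probes, 122 without 0 Gy replicate 3, 28 without 2 Gy replicate 2, 12 without 6 Gy replicate 4, and, as chosen after seeing the data, 163 without the first 2 of these arrays and 11 for the differences within slides.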

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

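The tests of labelling yield, of the side of the slide, of a swap of 2 arrays and of exchanges within pairs were chosen after the results were seen. Of 324 sets of 4 arrays, 49 held an array far from the other 3, where chance gives about 16.2, and 26 of the 49 belonged to 2 Gy replicate 2 and 8 to 0 Gy replicate 3. In 14 of the 49 the other 3 arrays lay at the floor, so any value above it counted as far, by gaps from 0.036 to 4.03, and these cannot be set against the 16.2 expected by chance, which leaves 35. Many miRNAs stood apart on the same arrays, so the 49 are not independent. In 2 Gy replicate 2 the values far from the rest were 0.38 for let-7b-5p, -1.25 for let-7c-5p, -2.08 for let-7i-5p, -1.96 for miR-100-5p, -1.01 for miR-125b-5p, -3.93 for miR-1274a_v16.0, -1.04 for miR-17-5p, -2.57 for miR-183-5p, -1.22 for miR-200c-3p, -2.64 for miR-21-5p, -1.17 for miR-210-3p, -3.30 for miR-221-3p and -1.73 for miR-23a-3p. Further values there were -0.57 for miR-24-3p, -1.33 for miR-25-3p, -3.74 for miR-27b-3p, -2.83 for miR-30c-1-3p, -3.85 for miR-30e-5p, -2.28 for miR-31-5p, 0.51 for miR-320d, -0.071 for miR-320e, -1.86 for miR-34a-5p, 0.27 for miR-3610, -3.17 for miR-425-5p, 1.69 for miR-483-5p and -1.55 for miR-93-5p. In 0 Gy replicate 3 they were -3.23 for miR-100-5p, -3.43 for miR-125b-5p, -2.67 for miR-17-5p, -3.29 for miR-25-3p, -1.87 for miR-29a-3p, -2.71 for miR-30c-1-3p, -4.60 for miR-31-5p and 2.30 for miR-3195. In 6 Gy replicate 2 they were -2.93 for let-7i-5p, -2.75 for miR-183-5p, -4.11 for miR-27b-3p and -2.49 for miR-34a-5p. In 0 Gy replicate 1 they were 1.64 for miR-134-5p, -3.23 for miR-422a and -0.49 for miR-601. In 10 Gy replicate 4 they were -1.72 for miR-141-3p, -4.60 for miR-24-3p and -4.60 for miR-31-5p. Others were -2.88 for miR-155-5p in 6 Gy replicate 1, and -4.08 for miR-3617-5p in 6 Gy replicate 4. Marked only because the other 3 lay at the floor of -4.60, and close to it themselves, were -4.48 for miR-1274a_v16.0 in 6 Gy replicate 2 and, for miR-92b-3p, -4.57 in 6 Gy replicate 4 and -4.56 in 10 Gy replicate 2.

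0 Gy replicate 3 and 2 Gy replicate 2 stood apart from their doses in opposite directions. Over the tested miRNAs 0 Gy replicate 3 correlated with the other 0 Gy arrays at 0.902 to 0.907 and with the other 2 Gy arrays at 0.986 to 0.987, and 2 Gy replicate 2 correlated with the other 2 Gy arrays at 0.939 to 0.947 and with the other 0 Gy arrays at 0.962 to 0.978 (mean 0.972). Both lay nearer every array of the opposite dose, which met the test of a swap of these 2 arrays between the doses. However, 0 Gy replicate 3 also correlated with the 6 Gy arrays at 0.969 to 0.987, so its likeness was not particular to 2 Gy. The other 2 Gy arrays correlated among themselves at 0.997 to 0.998, which 0 Gy replicate 3 did not reach. The other 0 Gy arrays did so at 0.977 to 0.991, which 2 Gy replicate 2 mostly did not reach. These comparisons were not part of that test, and a swap stays an open hypothesis. With the labelling spike-in as a covariate the deviation of the family mean of 0 Gy replicate 3 went from -1.69 to 0.047, and that of 2 Gy replicate 2 from 1.44 to 0.93 (SD of all residuals 0.42), so labelling yield cannot be told apart from the other sources for the first array and leaves 64.7% for the second. A difference between the cultures themselves stays open and untested.

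In this paragraph an SE beside a median is the median of the SEs of the single miRNAs, not the SE of that median. The falls at 2 and 6 Gy were the largest changes in size, with medians of -1.52 (median SE 0.34) for the 19 falls at 2 Gy and -1.29 (0.36) for the 38 at 6 Gy. The values argue against scaling as their whole cause, as the medians without it were -1.35 (SE 0.35) and -1.11 (0.40), although no fall was then called, as 16 of 19 and 27 of 38 kept an unadjusted p under 0.05 while such p-values over all miRNAs went from 99 to 36 and from 118 to 62, and the lowest adjusted p of a fall was 0.0642 and 0.0562. Position was checked with the 10 Gy arrays. The falls at 2 Gy had a median of 0.60 (SE 0.34) in 10 Gy against 6 Gy, between the same sides of a slide. Those at 6 Gy had 0.47 (SE 0.36) in 10 Gy against 2 Gy, which shares their slide step. Neither is the fall that an equal side or slide step alone would give, but the floor limits this check. At 2 Gy miR-100-5p, miR-125b-5p, miR-21-5p and miR-221-3p lay at the floor on every array but replicate 2. At 6 Gy miR-1274a_v16.0 lay there on every array but replicate 2. A further fall from the floor could not show, so such members cannot test position. Both medians rest on the 10 Gy arrays, whose labelling spike-in exceeded that at 6 Gy by 3.12 on the log2 scale. Each dose also had its own side of a slide, so position cannot be told apart from dose. With the labelling spike-in as a covariate the median at 2 Gy was -1.18 (SE 0.24) with 18 of 19 falls called. At 6 Gy it was -0.90 (SE 0.26, 69.4% of the fold kept) with 2 of 38 called. All 38 kept an unadjusted limma p under 0.05, while their median adjusted p went from 0.0407 to 0.0673. At least 1 spike-in was undetected on 4 arrays, and signals under 1 were set to 1. The covariate can therefore leave part of a labelling effect in the values. Labelling yield cannot be told apart from dose at 2 or at 6 Gy. An effect of dose on released miRNA stays open, as do labelling yield and position, which includes the slide that the design confounds with dose at 6 Gy. RNA from bovine serum stays open too and was not tested.

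The 10 Gy arrays lay closer to 0 Gy over the 39 falls called at 2 or 6 Gy, with a median of -0.74 at 10 Gy against -1.16 at 2 Gy and -1.26 at 6 Gy, but these miRNAs were selected at 2 and 6 Gy, which by itself makes the medians there larger. Over the 21 list miRNAs the means were -2.88, -3.18 and -2.04 at 2, 6 and 10 Gy. The 10 Gy mean differed from that at 6 Gy by 1.14 (exact two-sided permutation p = 0.0571, adjusted 0.114). In pairs of equal replicate number, chosen after seeing the data, all 4 differences lay above 0 (0.74 to 1.43). Exchanges within pairs gave an exact two-sided p = 0.125, the smallest possible. This mean was not among the comparisons fixed beforehand. It includes falls called at 6 Gy, so it is not free of selection either. With the labelling spike-in as a covariate the medians of the 39 falls were -0.89 at 2 Gy, -0.89 at 6 Gy and -0.80 at 10 Gy. The gap narrowed as the medians at 2 and 6 Gy shrank, which a higher labelling yield on the 10 Gy arrays could give. Their spike-in exceeded that at 6 Gy by 3.12 on the log2 scale (exact two-sided permutation p = 0.0286, the smallest possible, adjusted 0.114). The calls at 10 Gy against 0 Gy went from 1 to 56 with the covariate. Between these 2 doses the spike-in differed by 0.24 (exact two-sided permutation p = 0.971), so these calls do not show a difference in labelling yield. The direct test of 10 Gy against 6 Gy called no miRNA, and 55 in pairs of equal replicate number, chosen after seeing the data, a count that 1 of the 8 exchanges of doses within pairs reached, the real one (highest other 0), and 8 are too few to tell it from chance, so a biological difference between these doses stays open beside labelling yield.

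A chance assignment of arrays to doses was not excluded for the counts at 2, 6 and 10 Gy against 0 Gy. The 35 splits of the 8 arrays gave as many calls 2 times at 2 Gy (36 calls, highest other 165), 3 times at 6 Gy (55, highest other 142) and 2 times at 10 Gy (1, highest other 54). In each of these the highest other split exchanged 0 Gy replicate 3 with 1 irradiated array, which at 2 Gy was replicate 2, and its several-fold larger count points to a structure of the arrays. For 10 Gy against 6 Gy, the slope and the F test the real counts were 0, so all 35 splits (highest other 0) and all 100 regroupings (highest others 32 and 10) gave as many by construction and decide nothing. As values with no explanation, viral miRNAs detected on all arrays, 32 in number, had a median change of 0.10 (median SE of the single miRNAs 0.15) at 2 Gy and 0.16 (median SE 0.15) at 6 Gy, against 0.50 and 0.45 for the 17 rises called at each dose.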

How the results depend on the processing

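The normexp fit on median signals, the labelling spike-in covariate, the fit of differences within slides, the paired fit of 6 and 10 Gy, and the fits without the arrays with an undetected labelling spike-in or without 0 Gy replicate 3 and 2 Gy replicate 2 were chosen after seeing the data. Normexp on mean signals was not run. Counts below are given for 2 Gy, 6 Gy and 10 Gy against 0 Gy, against 36, 55 and 1. They were 19, 34 and 0 with normexp, 129, 177 and 22 with scaling over all probes, 0, 0 and 0 without scaling, 71, 127 and 27 with quantile normalization, 13, 10 and 6 with 4 times the floor, and 0, 0 and 3 with no filter. They were 26, 35 and 7 with probes detected on all arrays, 38, 66 and 9 with the brightest probe, 41, 88 and 0 with Agilent's total signal, 37, 55 and 3 with an intensity trend, and 203, 152 and 129 with array weights, whose estimation stopped before convergence. They were 54, 80 and 11 with the slide row as a block, and 0 in each with the arrays of the 2 doses alone, where fewer arrays estimate the spread. They were 54, 2 and 56 with the spike-in covariate, 116, 71 and 54 without arrays with an undetected spike-in, and 152, 166 and 70 without the 2 arrays that stood apart, which lowers the spread by construction. Replicate numbers did not pair the arrays, as 14 of 24 same-number pairs had a correlation of deviations over 0.1 (range -0.76 to 0.87) and 5 of 16 arrays lay closest to their own number, but all 4 pairs of 6 and 10 Gy lay over 0.1 (0.23 to 0.72). With the replicate block the counts were 68, 75 and 7, with 21 for the F test. For 10 Gy against 6 Gy the count of 0 became 55 in pairs, 1 (miR-3174, chosen after its value was seen) with no filter, 1 (miR-149-3p) with array weights and 1 (miR-149-3p) with the spike-in covariate. The slope's 0 became 91 with array weights and 1 (miR-3610) with the covariate, and stayed 0 with the slide or the dose rank. The F test's 0 became 104 with scaling over all probes, 43 with quantile normalization, 14 with 0.5 times the floor, 4 with 4 times the floor, 1 with no filter, 13 with probes detected on all arrays, 14 with the brightest probe, 9 with Agilent's total signal, 234 with array weights and 18 with the slide row. It was 37 with the covariate, 64 without arrays with an undetected spike-in, 163 without the 2 arrays that stood apart and 11 for differences within slides. Leaving out each array gave 0 to 121, 0 to 143, 0 to 43, 0 to 0, 0 to 0 and 0 to 122 for the 3 doses, 10 Gy against 6 Gy, the slope and the F test. Where a count was 0 the unadjusted p fell under 0.05 for 36 to 136, 62 to 166, 22 to 59, 9 to 95, 10 to 57 and 33 to 106 miRNAs. Differences in detected miRNAs ranged from -42.8 to -14.2, -41.5 to -18.5, -43.8 to -17.5 and -16 to 13.5 for the 4 dose pairs, and in unscaled log2 signal from -0.043 to 0.24, 0.12 to 0.47, -0.37 to -0.09 and -0.70 to -0.34. Over all probes the unscaled difference was -0.28 at 2 Gy and -0.13 at 6 Gy. Lists past the preset test numbered 2, 7, 1, 0 and 1 (the last 2 for 10 against 6 Gy and the slope), 0 in each with an estimated correlation, 6 without scaling and 6 with quantile normalization at 2 Gy, and 7 and 4 for 10 against 6 Gy. The median fold change of all miRNAs, 0.03, 0.12 and -0.02, was 0.40, 0.47 and 0.18 with scaling over all probes, 0.21, 0.22 and 0.09 with quantile normalization and 0.13, 0.37 and -0.23 without scaling. Of 6870 alternative values of 200 named miRNA and comparison pairs, 5693 kept direction and side of the threshold, 686 lost the call, 415 gained one, 76 (of 33 pairs) changed sign with neither value past the threshold and 0 changed sign past it. The cause was not tested except where stated. At most 26.4% of an array's spots were well above background, which limits the tested miRNAs to 283 of 1205.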

Other observations

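Among the 23 miRNAs called lower or higher at both 2 and 6 Gy, several of the lower ones that lie outside the lists were chosen here after their values were seen. miR-4284 was lower by 1.16 and 1.24 on the log2 scale at 2 and 6 Gy, miR-4299 by 1.21 and 1.19, miR-181b-5p by 0.83 and 0.86, and miR-196b-5p, of a HOX cluster, by 0.64 and 0.77. Their values at 10 Gy were -1.01, -0.80, -0.25 and -0.37, and none was called there. The 5 called higher at both doses had been named by the fixed rule, and miR-134-5p is in the GC-rich list. They were miR-765, miR-711, miR-601, miR-134-5p and miR-1226-5p, with 0.58, 0.46, 0.45, 0.52 and 0.45 at 10 Gy without passing. miR-539-5p was lower at both (-0.35 and -0.34) and had -0.35 at 10 Gy.

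Viral miRNA probes serve as a measure of signal not owed to the named target in a human cell line. Of 142 viral miRNAs, 32 to 43 were detected on each array, with means of 38.8 ± 2.75 at 0 Gy, 39.2 ± 2.22 at 2 Gy, 40.5 ± 4.36 at 6 Gy and 36.5 ± 3.00 at 10 Gy (SD, n = 4), and no dose exceeded the highest 0 Gy array in its mean. The smallest p was 0.2 (adjusted 0.8, exact two-sided permutation test), for 10 Gy against 6 Gy.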
